A study of Mus musculus with 9 samples.

How the data were processed

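Gene expression was measured in cells recovered with CD8a magnetic beads from MC38 tumours of male C57BL/6N mice. MC38 is a mouse colon carcinoma line, and the tumours had been grown under the skin and were taken 21 days after injection. Per the labels' protocols, the tumours were digested with collagenase D and dispase and red blood cells were lysed before the beads were added. The 9 libraries fall into 3 groups of 3: mice of 5 months fed ad libitum (young, ad libitum), mice of 20 months fed ad libitum (aged, ad libitum) and mice of 20 months given 70% of the ad libitum intake (aged, restricted). Libraries were made with the QuantSeq 3′ kit, which reads the 3′ end of polyadenylated transcripts, and were sequenced as single reads of 75 bp.

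The deposited values are counts of reads per gene, 1 column per library, and are whole numbers that sum to a different total in each library. Per the submitters' processing notes, Trim Galore, STAR and featureCounts were used, with GRCm38 (mm10) as the genome. No versions of these tools, and no use of strand, of reads with several matches or of molecular identifiers, are given in the sources used here. Without molecular identifiers, copies made by PCR count as separate reads, so the floors and the intervals on read counts given here cover counting error only. A 3′ method gives counts that do not scale with transcript length, and no length correction was made. The file lists 25361 genes with coordinates. Of the 25268 genes (99.6%) whose identifiers were found in GENCODE M21, an annotation of GRCm38, 536 (2.12%) had the same start and end. The coordinates printed here are therefore those of the file, whose build is not established, and none were converted. All 226 T cell receptor genes and all 268 immunoglobulin genes that the annotation shares with the file were at 0 counts in all 9 libraries, so receptor transcripts, including the constant regions, were not measurable here.

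Library totals ran from 810662 to 1258575 counts, and from 471293 to 962370 counts without the mitochondrially encoded genes. Of the 14418 genes with a count in any library, 9009 passed edgeR's filterByExpr (minimum count 10, by group) and were tested. The biological coefficient of variation was 40.5%. Any 2 libraries of the same group differed by more than sampling noise (chi-square per degree of freedom at least 5.67), so no library was taken for a copy of another. The series' design text describes the replicates as biological and independent.

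Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood F-test) in a one-way model of all 9 libraries with 6 residual degrees of freedom. The contrasts were aged against young, both ad libitum; restricted against ad libitum, both aged; and aged restricted against young ad libitum. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a contrast, at a threshold of 0.05 with no minimum fold. Gene levels are means in TMM-scaled CPM (counts scaled to a common library size of 1e6) with the SD over the 3 libraries of a group, and list levels are summed CPM of the plain library total. For a group at 0 counts, a bound was computed against a floor of 3 counts over the group, and for a group at 1 to 3 counts the ratio is given with a 95% counting interval (exact binomial). A gene that shares reads with a near-identical copy is reported as uncertain.

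The 33 gene lists, with 688 genes, were tested with limma 3.58.1 on log2 CPM (prior count 2), by camera with a preset correlation of 0.01 between genes, by camera with an estimated correlation, and by fry. Camera compares the genes of a list with all other tested genes. Fry tests whether the genes of a list move, on balance, in 1 direction. Adjusted p-values of lists were computed over the 29 lists with at least 3 tested genes within a contrast; the other 4 lists (B and plasma cells, NK and gamma-delta T cells, tumour epithelium, CD4 and regulatory T cells) had from 0 to 2 tested genes. Single summary values were compared with exact 2-sided permutation tests. With 3 libraries against 3 the smallest p these can give is 0.1, so they cannot reach 0.05. The family held 18 such comparisons.

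The groups, the tests, the 33 lists, the alternatives other than those named as later, and the rule for named genes were fixed before the data were examined. The rule took, per contrast, up to 10 called genes with the largest rise and 10 with the largest fall, with all 3 libraries of 1 group above all 3 of the other and a mean of at least 10 CPM; up to 4 genes per list with the smallest p-values; and 12 genes of CD8 T cells in every contrast. Predicted gene models were left out, and the text prints only part of the genes that the rule names. A gene outside this rule is named as chosen after its values were seen. Lists of skin, skeletal muscle, T cell core and T cell effector genes, and second lists of macrophage, skin and muscle genes, were added after the data had been seen.

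The test was checked on simulated counts drawn from the means and library sizes of the 9009 genes, with 200 genes of at least 10 CPM changed. Of 100 genes changed 4-fold it recovered 53% for the age contrast, 55% for the restriction contrast and 56% for the contrast of restricted and young mice. Of 100 genes changed 2-fold it recovered 18%, 6% and 13% in the same order. The false calls numbered 3, 3 and 4. Recovery of genes under 10 CPM was not measured. The alternatives were other scalings, no filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma voom with sample weights, a fit of only the 2 groups compared, the replicate number as a block, the mean macrophage list level as a covariate, a minimum log2 fold change of 1, and each library left out in turn. Leaving out mitochondrial genes and thinning every library to the smallest total were added later. The submitters' reads, quality scores and alignments were not used here.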

Results

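The series measured how age and caloric restriction alter the transcripts of cells that CD8a beads recovered from MC38 tumours. Total counts were 1220634, 1232975 and 1212238 in the young ad libitum libraries, 908514, 818450 and 810662 in the aged ad libitum libraries, and 1091933, 1258575 and 1145549 in the aged restricted libraries. The aged ad libitum libraries were thus the shallowest. A single count was worth from 0.795 to 1.23 CPM. Mitochondrially encoded genes took 35.6% ± 3.2, 36.7% ± 5.74 and 35.6% ± 11.2 of the counts (SD, n = 3) in the young, aged ad libitum and aged restricted groups. In single libraries this share ran from 23.53% (exact 95% binomial interval 23.46 to 23.61) in aged restricted replicate 2 to 45.67% (45.57 to 45.76) in replicate 1 of the same group.

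CD8 T cell transcripts were scarce in all 3 groups, and transcripts of macrophages exceeded them. Cd8a, a chain of the CD8 co-receptor that the beads bind, had 54, 11 and 5 counts in the young libraries, 59, 4 and 32 in the aged ad libitum libraries and 47, 51 and 53 in the aged restricted libraries. The T cell identity list (CD3 and CD8 chains, proximal signalling genes) summed to 172 ± 120, 302 ± 190 and 434 ± 114 CPM (SD, n = 3) in young, aged ad libitum and aged restricted mice. The monocyte and macrophage list (C1q chains, Csf1r, Lyz2, Apoe) summed to 4558 ± 210, 4610 ± 2208 and 10595 ± 912 CPM in the same order. Aged ad libitum replicate 2 was the lowest of its group for both lists, at 149 and 2521 CPM. Each gene level below is over all cells of a sample. The exact 2-sided permutation test of the macrophage level gave p = 0.9 for age, 0.1 for restriction and 0.1 for restricted against young mice, and that of the T cell level gave p = 0.4, 0.4 and 0.1. The smallest p that 3 libraries against 3 can give is 0.1, and over the 18 comparisons of this family each p of 0.1 became 0.18 after adjustment.

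Levels of other marker lists are given next. The skin keratinocyte list stood at 10.4 ± 3.37, 117 ± 43.2 and 613 ± 405 CPM (SD, n = 3) in young, aged ad libitum and aged restricted mice, and the skeletal muscle list at 23.1 ± 11 CPM, 102 ± 53.4 CPM and 356 ± 262 CPM. Both lists were chosen after the data had been seen, and each of their comparisons gave an exact permutation p of 0.1. The red blood cell list, fixed beforehand, stood at 2.46 ± 4.26, 71.2 ± 25.1 and 287 ± 113 CPM, although the protocol included a lysis of red blood cells. Endothelial genes were at 127 ± 34.5, 510 ± 236 and 216 ± 123 CPM. Fibroblast genes were at 2052 ± 208, 2055 ± 439 and 1797 ± 1048 CPM. Epithelial genes expected of a colon tumour summed to 8.74 ± 7.35, 19.6 ± 5.41 and 35 ± 28 CPM, and B and plasma cell genes to 2.71 ± 4, 9.23 ± 5.5 and 5.89 ± 2.47 CPM. No library here was of MC38 cells alone, so the epithelial sum does not give the share of tumour cell RNA. CD4 and regulatory T cell genes summed to 28.1 ± 17.9, 55.1 ± 35.9 and 66.8 ± 18.8 CPM, and NK and gamma-delta T cell genes to 6 ± 9.03, 6.86 ± 5.5 and 3.76 ± 1.52 CPM. The lists of B and plasma cells, of NK and gamma-delta T cells and of T cell identity include immunoglobulin or T cell receptor genes. Those genes were at 0 counts in all libraries, so these sums leave them out and do not show how few such cells there were.

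**Figure D1:**
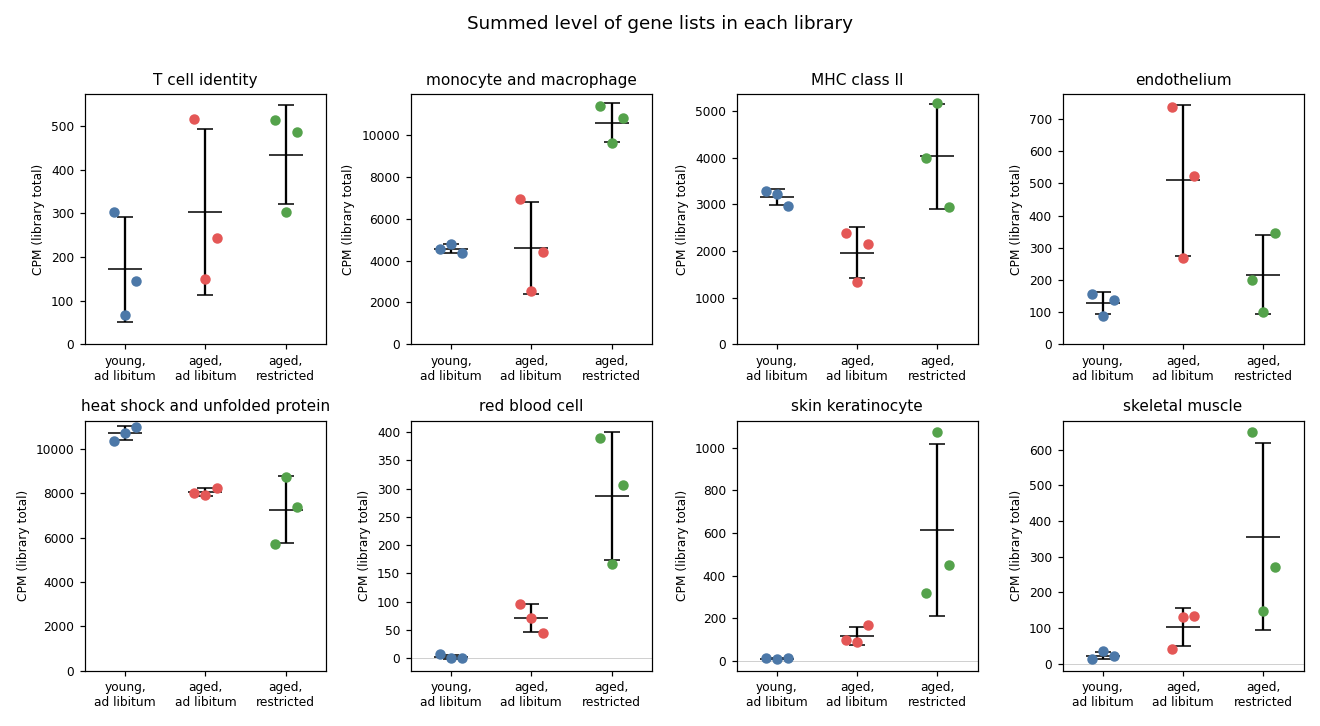
Summed CPM of the library total (vertical axis) of 8 gene lists in each of 9 libraries, with the mean and SD of 3 libraries per group in black. The 3 aged restricted libraries lie between 9601 and 11394 CPM for the macrophage list, above the other 6 libraries, and the 3 young libraries lie above the 3 aged ad libitum libraries for the heat shock list.

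The comparison of aged with young mice, both fed ad libitum, asked what age alone changed. Inducible heat shock genes fell with age. Hspa1a, which encodes a stress-induced HSP70 chaperone, went from 195 ± 51.3 CPM in young to 10.1 ± 2.92 CPM in aged mice (SD, n = 3). Its neighbour Hspa1b went from 271 ± 60.1 to 40.3 ± 10.3 CPM. Dnajb1, an HSP40 co-chaperone, went from 241 ± 29.5 to 83.8 ± 9.19 CPM. Stc1 and Igfbp3, which encode the secreted proteins stanniocalcin and an IGF-binding protein, rose from 19.5 ± 10.9 to 119 ± 45.3 CPM and from 60.2 ± 27.6 to 265 ± 106 CPM. None of the 9 CD8 T cell genes on the fixed list that were deep enough to test passed the threshold. In all, 26 of 9009 genes passed the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 13 up and 13 down, 24 of them by at least 1 on the log2 scale.

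The heat shock and unfolded protein list had the most called genes and the smallest camera p of the lists that were lower with age. Of its 23 tested genes 4 fell and none rose, or 11 fell when adjusted over the list alone, and 19 had a lower fitted level in aged mice, with a median log2 fold change of -0.58. The 4 were Hspa1a (log2 fold change -4.28 ± 0.39 SE, edgeR adjusted p = 1.66e-07), Hspa1b (-2.76 ± 0.31, adjusted p = 7.31e-06), Dnajb1 (-1.52 ± 0.27, adjusted p = 0.00767) and Hspe1, the mitochondrial HSP10 (-0.87 ± 0.19, adjusted p = 0.0303). The list passed camera at an adjusted p = 7.9e-07, with adjusted p = 0.03 with an estimated correlation and 3.85e-04 by fry. Hspa1a lies on chromosome 17 at 35188166 to 35191132 on the minus strand in the file's coordinates, beside Hspa1b at 35175412 to 35178214. The pair are near-identical copies whose reads the counting could have split. Summed, they stood at 458 ± 124 CPM of the library total in young and 49.6 ± 8.67 CPM in aged mice (SD, n = 3), with every aged library below every young library.

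Other genes that fell with age were spread over several functions. Tuba1b, an alpha-tubulin, fell from 1554 ± 4.81 to 769 ± 129 CPM (SD, n = 3), although other tubulin genes share part of its sequence. Cx3cr1, the fractalkine receptor of monocytes and of some effector T cells, fell from 228 ± 11.2 to 102 ± 21.8 CPM (SD, n = 3). It was the 1 called gene of 10 in the chemokine receptor list, and 1 when adjusted over the list alone (camera adjusted p = 0.639). H2-Eb1, a beta chain of MHC class II, fell from 691 ± 48.8 to 353 ± 62.7 CPM, as the 1 called gene of its list. All 6 tested genes of the MHC class II list had a lower fitted level (1 called, 3 when adjusted over the list alone). By camera the list passed at adjusted p = 0.0105, and had adjusted p = 0.47 with an estimated correlation. Crabp1, Med16, Rraga, Or2w1b and Hmgn2 also fell, by 1.39, 2.02, 1.56, 2.02 and 2.81 on the log2 scale. Hmgn2 has a near-identical pseudogene in the file, and the sum of the pair stood at 139 ± 43.2 CPM of the library total in young and 72.3 ± 5.56 CPM in aged mice, so its fall is uncertain.

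Endothelial and red blood cell genes had higher fitted levels in aged mice. Esm1, an endothelial proteoglycan, rose from 1.14 ± 0.99 to 40.4 ± 23.9 CPM (SD, n = 3; log2 fold change 5.04 ± 0.95 SE, edgeR adjusted p = 0.0103). Col4a1, a basement membrane collagen, rose from 115 ± 41.7 to 276 ± 50.5 CPM (adjusted p = 0.043). All 10 tested endothelial markers had a higher fitted level in aged mice, at a median of 1.84 on the log2 scale; none of them passed the threshold over all genes and 9 did when adjusted over the list alone. The endothelium list passed camera at adjusted p = 4.75e-08, and had adjusted p = 0.33 with an estimated correlation. Flt1, a VEGF receptor, stood at 30.5 ± 6.38 CPM in young and 103 ± 17.5 CPM in aged mice without passing (adjusted p = 0.0666). Of 4 red blood cell genes, Hba-a2 and Hbb-bs rose and 4 did when adjusted over the list alone; the list had a camera adjusted p = 3.18e-05 and adjusted p = 0.33 with an estimated correlation. The globin genes have near-identical copies, and the sum of Hba-a1 and Hba-a2 went from 1.09 ± 1.89 CPM to 44.3 ± 10.6 CPM of the library total.

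Fosb, an immediate-early transcription factor, rose from 170 ± 29.1 to 456 ± 54.9 CPM (SD, n = 3; log2 fold change 1.43 ± 0.24 SE, edgeR adjusted p = 0.00625). It was the 1 gene of 17 in its list to change, also when adjusted over the list alone. That list had a camera adjusted p = 0.0789 and adjusted p = 0.7 with an estimated correlation. Ccnl1, a cyclin linked to splicing, rose from 45.8 ± 12 to 159 ± 37.4 CPM, and Sestd1 from 6.19 ± 2.64 to 37.8 ± 18.6 CPM. Igfbp3 was the 1 called gene of 17 in the senescence and inflammatory secretion list, and 1 when adjusted over the list alone (camera adjusted p = 0.0884). S100a8, an alarmin of neutrophils, had 0 counts over the young libraries and 41 over the aged ones, at least 19.3-fold higher. The neutrophil list (1 called of 3 tested, 2 when adjusted over the list alone) had a camera adjusted p = 0.00999 and adjusted p = 0.35 with an estimated correlation. The remaining 4 called genes were listed after their values were seen. Retnla had 50 counts over the young libraries and 0 over the aged ones, at least 11.8-fold lower. Krt14 and Krt17, keratins of the epidermis, had 0 counts in young mice and were at least 16.9-fold and at least 12.2-fold higher. Lgals7 had 2 counts against 42, a ratio of 29.6 with a counting interval of 7.7 to 252.

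Several lists of housekeeping functions were lower in aged mice. Nuclear genes of oxidative phosphorylation had a median log2 fold change of -0.32, with 47 of 56 lower and none called, also when adjusted over the list alone (camera adjusted p = 2.86e-04, adjusted p = 0.33 with an estimated correlation, fry 0.0334). Ribosomal protein genes had a median of -0.20, with 70 of 82 lower, none called and 2 when adjusted over the list alone (camera adjusted p = 0.00897, adjusted p = 0.7 with an estimated correlation). Proliferation genes had 26 of 34 lower (median -0.33) and cholesterol synthesis genes 16 of 22 (median -0.61), with none called in either, also when adjusted over the list alone. Both had a camera adjusted p = 0.0145, with adjusted p = 0.35 with an estimated correlation for proliferation and adjusted p = 0.47 with an estimated correlation for cholesterol synthesis. Mki67, a proliferation marker, stood at 129 ± 17.4 CPM in young and 154 ± 6.7 CPM in aged mice (SD, n = 3; edgeR adjusted p = 0.789).

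The T cell lists did not pass with age. The T cell identity list had 11 of 13 genes higher in aged mice, at a median of 0.87 on the log2 scale, none called, also when adjusted over the list alone, and a camera adjusted p = 0.0505. The inhibitory receptor and exhaustion list had none of 11 called, 1 when adjusted over the list alone (camera adjusted p = 0.0789). The cytotoxic effector list had a median of 0.31 but a camera direction of down (adjusted p = 0.922), with none of 16 called and 1 lower when adjusted over the list alone. Cd8a stood at 19.3 ± 22.1 CPM in young and 34.9 ± 27.6 CPM in aged mice, with edgeR adjusted p = 0.77 (SD, n = 3). Pdcd1 stood at 9.2 ± 10.1 and 18.7 ± 22.6 CPM and Gzmb at 17.4 ± 15 and 28 ± 24.3 CPM, with edgeR adjusted p = 0.794 and 0.87. Lag3, Tox and Tcf7 were too low to test, with single libraries of the series at 0 to 13 counts. The macrophage list had 12 of 20 genes higher and none called, also when adjusted over the list alone (camera adjusted p = 0.86, and 0.0223 upward without aged replicate 2). The age calls rested on few libraries: 2 genes, Hspa1a and Hspa1b, were called without young replicate 2, 3 without aged replicate 3 and 9 without young replicate 3. DESeq2 called 91 genes, and scaling by library totals 19, 12 up and 7 down.

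**Figure D2:**
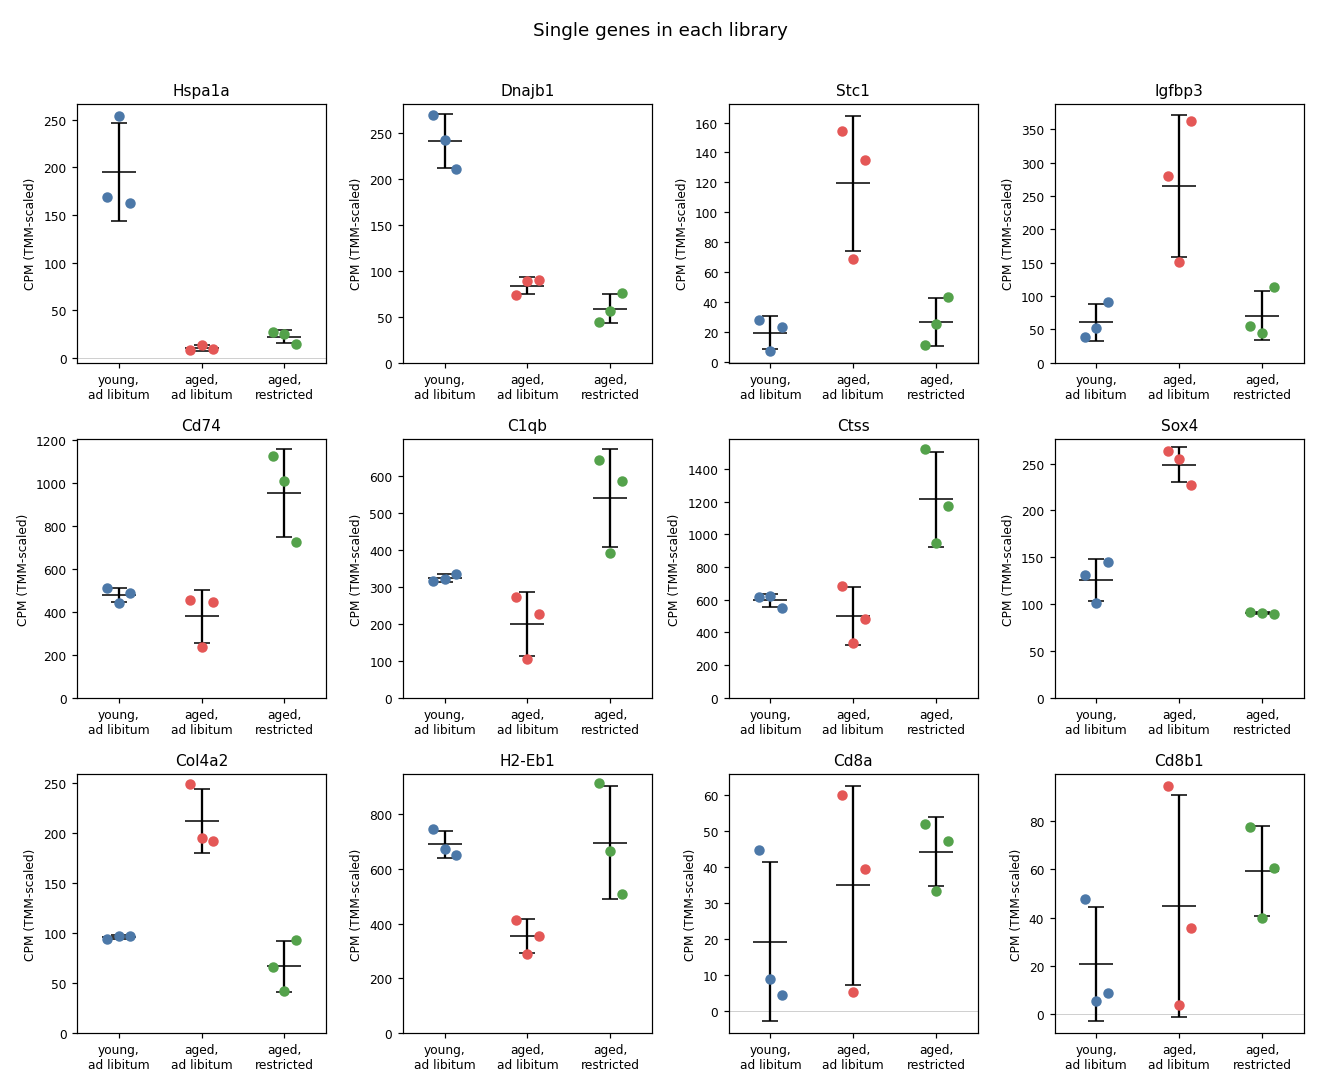
TMM-scaled CPM (vertical axis) of 12 genes in each of 9 libraries, with the mean and SD of 3 libraries per group in black. Hspa1a and Dnajb1 lie lower in both aged groups than in young mice, Cd74, C1qb and Ctss lie highest in aged restricted mice, and Cd8a and Cd8b1 overlap between groups.

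The comparison of restricted with ad libitum feeding, both in aged mice, asked what caloric restriction changed at that age. Of the macrophage list 6 of 20 genes rose and of the MHC class II list 4 of 6, and each list had adjusted p = 0.39 with an estimated correlation. Ctss, a lysosomal protease, went from 500 ± 176 to 1215 ± 291 CPM (SD, n = 3). Cd74, the invariant chain of MHC class II, went from 379 ± 124 to 954 ± 205 CPM. Col4a2, a basement membrane collagen, fell from 211 ± 31.8 to 66.4 ± 25.6 CPM, and Flt1, a VEGF receptor of endothelium, from 103 ± 17.5 to 26.8 ± 16.3 CPM. Sox4, a transcription factor, fell from 249 ± 18.8 to 90.8 ± 1.05 CPM. In all, 85 genes passed the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 62 up and 23 down, 75 of them by at least 1 on the log2 scale and 1 of them a predicted gene model. None of the 9 tested genes of the fixed CD8 T cell list was among them.

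All 20 tested genes of the monocyte and macrophage list had a higher fitted level in restricted mice, with a median log2 fold change of 1.22; 6 rose, or 11 when adjusted over the list alone. The complement genes C1qb and C1qc rose by 1.42 ± 0.26 (SE, edgeR adjusted p = 0.00548) and 1.38 ± 0.26 (adjusted p = 0.00707). The list passed camera at adjusted p = 4.69e-10, and had adjusted p = 0.39 with an estimated correlation. The summed list level was 4610 ± 2208 CPM in ad libitum and 10595 ± 912 CPM in restricted mice (SD, n = 3). Of 6 MHC class II genes 4 rose, or 5 when adjusted over the list alone. Cd74 rose by 1.33 ± 0.22 (SE, edgeR adjusted p = 0.00163), H2-Aa from 561 ± 164 to 1186 ± 274 CPM, H2-Ab1 from 571 ± 97.6 to 1075 ± 247 CPM and H2-Eb1 from 353 ± 62.7 to 697 ± 206 CPM (SD, n = 3). Their list passed camera at adjusted p = 3.82e-04, and had adjusted p = 0.39 with an estimated correlation. Of 24 autophagy and lysosome genes, Ctsd and Lamp1 rose, and 4 did when adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.39 with an estimated correlation, fry 0.0414).

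Retnla and Chil3, both known from alternatively activated macrophages, were among the largest rises. Retnla, a resistin-like protein, had 0 counts over the aged ad libitum libraries and 157 over the restricted libraries, at least 37.5-fold higher. Chil3, a chitinase-like protein, rose from 6.23 ± 4.93 to 108 ± 72.4 CPM (SD, n = 3; log2 fold change 4.03 ± 0.71 SE, edgeR adjusted p = 0.00707). Gpx3, a secreted glutathione peroxidase, rose from 8.23 ± 1.57 to 76.7 ± 30.7 CPM, and complement C3 from 4.61 ± 1.31 to 47.2 ± 17.2 CPM. Sla, an adaptor that dampens antigen receptor signalling, rose from 5.27 ± 2.41 to 52.6 ± 12.4 CPM. Haptoglobin (Hp) rose from 2.03 ± 3.52 to 37.5 ± 21.4 CPM. Hmgn2 rose from 12.2 ± 4.56 to 116 ± 89.4 CPM; with its pseudogene, the sum was 72.3 ± 5.56 and 161 ± 32.9 CPM of the library total, so its rise is uncertain. Trdn, a gene of the muscle calcium release complex, rose from 3.8 ± 2.85 to 45.9 ± 37.2 CPM, and Calm4, an epidermal calcium-binding protein, had 0 and 87 counts, at least 20.8-fold higher.

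Klrk1, the activating receptor NKG2D of CD8 T and NK cells, rose from 2.77 ± 1.42 to 32.1 ± 29.8 CPM (SD, n = 3; log2 fold change 3.46 ± 0.78 SE, edgeR adjusted p = 0.0227). It was the 1 called gene of 16 in the cytotoxic effector list, where 5 rose when adjusted over the list alone and 15 had a higher fitted level. By camera the list passed at adjusted p = 3.82e-04, and had adjusted p = 0.39 with an estimated correlation. Gzmb stood at 28 ± 24.3 CPM in ad libitum and 44.7 ± 27.4 CPM in restricted mice. Ifng stood at 8.04 ± 6.76 and 9.62 ± 6.65 CPM and Prf1 at 11.8 ± 17.1 and 12.1 ± 4.31 CPM. The edgeR adjusted p of these 3 genes ran from 0.868 to 0.999. Cd8a (34.9 ± 27.6 and 44.2 ± 9.63 CPM), Cd8b1 (44.8 ± 46 and 59.3 ± 18.8 CPM) and Cd3e (10.9 ± 14.4 and 27.4 ± 3.85 CPM) were not called either. Pdcd1 and Havcr2, inhibitory receptors, stood at 18.7 ± 22.6 and 34.1 ± 17 CPM and at 7.43 ± 7.14 and 15.3 ± 6.7 CPM. The T cell identity list had 11 of 13 genes higher and none called, also when adjusted over the list alone (camera adjusted p = 0.0697). The lists of chemokine receptors (none of 10 called, 2 when adjusted over the list alone), NK-type receptors (none of 5, 2) and naive and memory genes (none of 12, 1) passed camera upward at adjusted p = 0.00336, 0.0219 and 0.0223. Their values were adjusted p = 0.39, 0.39 and 0.47 with an estimated correlation.

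All 10 endothelial markers had a lower fitted level in restricted mice (median log2 fold change -1.05), with Flt1 called and 1 called when adjusted over the list alone. The endothelium list passed camera at adjusted p = 3.82e-04, and had adjusted p = 0.39 with an estimated correlation. Col4a2 fell by 1.68 on the log2 scale (SE 0.29, edgeR adjusted p = 0.00226), Sox4 by 1.45 (SE 0.25, adjusted p = 0.00214). Sparc, a matrix protein, fell from 825 ± 210 to 399 ± 56.7 CPM (SD, n = 3) and was the 1 called gene of 11 in the fibroblast list, and 1 when adjusted over the list alone (camera adjusted p = 0.226). Apln, the ligand of the apelin receptor, fell from 55.2 ± 38.6 to 7.66 ± 4.58 CPM, Stc1 from 119 ± 45.3 to 26.5 ± 16.3 CPM and Igfbp3 from 265 ± 106 to 70.4 ± 37.2 CPM. Col7a1, an anchoring collagen, fell from 91.9 ± 37.5 to 27.4 ± 6.22 CPM, Syne1, a nuclear envelope protein, from 236 ± 41.1 to 90.8 ± 6.15 CPM, and Slc5a3, an inositol transporter, from 69.8 ± 15 to 25.5 ± 7.72 CPM.

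The glycolysis and hypoxia list had 19 of 22 genes lower (camera adjusted p = 0.00336, adjusted p = 0.48 with an estimated correlation). Its 1 called gene, Hif1a, the transcription factor of the hypoxia response, rose from 14.4 ± 4 to 54.5 ± 4.04 CPM (SD, n = 3; edgeR adjusted p = 0.0227). When adjusted over the list alone, 1 rose and 2 fell. Cholesterol synthesis genes had 16 of 22 lower and none called, also when adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.41 with an estimated correlation). Of 17 genes of the amino acid response and serine pathway Mthfd2, a mitochondrial folate enzyme, fell, and 1 fell when adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.39 with an estimated correlation). Zfp36 rose in the immediate-early list (1 of 17, 6 when adjusted over the list alone) and Dusp1 in the glucocorticoid-induced list (1 of 12, 3 up and 1 down when adjusted over the list alone). These lists passed camera upward at adjusted p = 0.0219 and 0.0402, and had adjusted p = 0.47 and 0.39 with an estimated correlation. The red blood cell list (none of 4 called, 3 when adjusted over the list alone) and the neutrophil list (none of 3, also when adjusted over the list alone) passed upward at adjusted p = 3.82e-04 and 0.0298, each with adjusted p = 0.39 with an estimated correlation. The heat shock list did not pass (adjusted p = 0.388): Hspa1a and Hspa1b together stood at 49.6 ± 8.67 CPM of the library total in ad libitum and 50.5 ± 3.14 CPM in restricted mice.

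Rps27 had 1580, 1606 and 515 counts in young, 749, 448 and 180 in aged ad libitum and 1, 9 and 2 in restricted libraries, and fell with restriction (edgeR adjusted p = 0.022). Rps27rt, a near-identical copy, stood at 1195 ± 156, 1501 ± 273 and 1776 ± 335 CPM of the library total in the 3 groups (SD, n = 3). The sum of both stood at 2202 ± 388, 2032 ± 209 and 1779 ± 338 CPM (exact permutation p = 0.3 for restriction), so the fall of Rps27 alone is uncertain. Rpl35, also a ribosomal protein gene, fell from 1509 ± 111 to 918 ± 195 CPM (edgeR adjusted p = 0.0227). With these 2 genes called, and 2 when adjusted over the list alone, the ribosomal list of 82 genes had a median of 0.07 on the log2 scale and a camera direction of down (adjusted p = 0.947).

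The restriction calls were lost when the level of macrophage genes was added to the model. With the mean macrophage list level of each library as a covariate, 1 gene was called, none of the 85. The median absolute log2 fold change of the 85 genes went from 1.52 to 0.992 and its median SE from 0.324 to 0.52. That level was 7.8 ± 0.286 in restricted and 6.49 ± 0.751 in ad libitum mice on the log2 scale (SD, n = 3), so the covariate follows the groups. Of the 85 genes, 83 kept their sign. The covariate fit thus cannot tell changes that track the macrophage level from a loss of precision. Without aged ad libitum replicate 2, 25 genes were called, without its replicate 3, 42, without restricted replicate 1, 31, without restricted replicate 3, 50, and without restricted replicate 2, 148. DESeq2 called 171, and scaling by library totals 50. Among the genes that stayed called without each library in turn (18 of 85) were Cd74, Ctss, C1qb, Gpx3, Retnla, Sla, Dusp1, Sox4, Col4a2 and Sparc.

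The comparison of aged restricted with young ad libitum mice combines age and feeding. All 4 red blood cell genes and 7 of 20 macrophage genes rose (lists at adjusted p = 0.084 and 0.22 with an estimated correlation), and 8 of 23 heat shock genes fell. Hspa1a stood at 195 ± 51.3 CPM in young and 21.9 ± 6.7 CPM in aged restricted mice (SD, n = 3) and Hspa1b at 271 ± 60.1 and 29.2 ± 8.27 CPM. The chemokines Ccl3 and Ccl4 rose from 30.4 ± 12.3 to 128 ± 55.1 CPM and from 42 ± 9.42 to 152 ± 59.7 CPM, and the cytokine Il1b from 140 ± 25.5 to 425 ± 160 CPM. In all, 175 genes passed the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 100 up and 75 down, 140 of them by at least 1 on the log2 scale and 1 of them a predicted gene model. Scaling by library totals called 117, 81 up and 36 down.

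Some of the genes that rose had 0 counts over the young libraries. Krtdap, a keratinocyte differentiation gene, was at least 119-fold higher. The keratin genes Krt14, Krt5 and Krt17 were at least 53.1-fold, at least 43-fold and at least 39.3-fold higher, and Dsp, a desmosome protein, at least 37-fold. Myh1, a fast myosin heavy chain of muscle, was at least 53.8-fold higher and Trdn at least 47.4-fold. The summed skin list level was 10.4 ± 3.37 CPM in young and 613 ± 405 CPM in aged restricted mice (SD, n = 3), and the muscle list level 23.1 ± 11 and 356 ± 262 CPM. Cd163, a scavenger receptor of tissue macrophages, was at least 50.1-fold higher, S100a8 at least 37.3-fold and Hba-a1 at least 67.6-fold. All 4 red blood cell genes rose, also when adjusted over the list alone, and with the 2 at their bounds (Hba-a1 and Hbb-bt) the median was 6.04 on the log2 scale. The list passed camera at adjusted p = 1.53e-09, and had adjusted p = 0.084 with an estimated correlation. The neutrophil list had 2 of 3 called, 2 when adjusted over the list alone (camera adjusted p = 3.59e-05, adjusted p = 0.13 with an estimated correlation).

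All 20 macrophage genes had a higher fitted level in aged restricted mice, with a median log2 fold change of 1.28; 7 rose, or 16 when adjusted over the list alone. Cd14, a co-receptor for lipopolysaccharide, rose from 31.4 ± 16.4 to 123 ± 30.4 CPM (SD, n = 3) and Csf1r, the receptor for macrophage growth factor, from 206 ± 41.8 to 415 ± 43.6 CPM. By camera the list passed at adjusted p = 1.43e-11, and had adjusted p = 0.22 with an estimated correlation. Of 17 immediate-early genes 4 rose, or 9 when adjusted over the list alone, among them Fosb (170 ± 29.1 to 452 ± 165 CPM) and Fos (178 ± 25 to 367 ± 22.1 CPM). The list passed camera at adjusted p = 1.03e-05, and had adjusted p = 0.23 with an estimated correlation. Il1b was the 1 called of 17 genes of the senescence and secretion list, with 3 when adjusted over the list alone (camera adjusted p = 9.23e-04, adjusted p = 0.11 with an estimated correlation). Of 32 interferon-stimulated genes Mx1 and Ifih1, an antiviral GTPase and an RNA sensor, rose, and 2 when adjusted over the list alone (camera adjusted p = 0.0258, adjusted p = 0.41 with an estimated correlation). Dusp1 and Sgk1 rose and Mt2 fell in the glucocorticoid-induced list of 12 tested genes (3 up and 1 down when adjusted over the list alone; camera upward, adjusted p = 0.0106, adjusted p = 0.23 with an estimated correlation). The endothelium list had none of 10 called, also when adjusted over the list alone (camera upward, adjusted p = 0.0324, adjusted p = 0.41 with an estimated correlation).

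T cell genes had higher fitted levels in aged restricted than in young mice without any called gene of T cell identity. All 13 genes of that list were higher, with 1 called when adjusted over the list alone. By camera the list passed at adjusted p = 8e-05, and had adjusted p = 0.29 with an estimated correlation. Cd3e stood at 7.82 ± 4.81 CPM in young and 27.4 ± 3.85 CPM in aged restricted mice (SD, n = 3; edgeR adjusted p = 0.34), and Cd8a at 19.3 ± 22.1 and 44.2 ± 9.63 CPM (adjusted p = 0.619). In the cytotoxic effector list Ccl3, Ccl4 and Srgn rose, 3 of 16 and 3 when adjusted over the list alone (camera adjusted p = 3.91e-04, adjusted p = 0.29 with an estimated correlation). With the macrophage covariate none of the 3 was called, and Ccl3 and Srgn turned to -0.50 and -0.31 on the log2 scale (edgeR adjusted p = 0.907 and 0.911). Cd38, an ectoenzyme also found on macrophages, was the 1 called of 11 genes of the inhibitory receptor and exhaustion list, and 1 when adjusted over the list alone, from 1.67 ± 2.18 to 29 ± 16.8 CPM (camera adjusted p = 0.00146, adjusted p = 0.28 with an estimated correlation). Ccr2, a receptor of monocytes, rose in the chemokine receptor list (1 of 10, 5 when adjusted over the list alone; camera adjusted p = 0.0289, adjusted p = 0.32 with an estimated correlation). The naive and memory list had none of 12 called, also when adjusted over the list alone (camera upward, adjusted p = 0.0424, adjusted p = 0.41 with an estimated correlation).

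Of the 23 heat shock genes 8 fell, or 10 when adjusted over the list alone, and 20 had a lower fitted level. Hspa1b fell by 3.23 on the log2 scale (SE 0.32, edgeR adjusted p = 6.89e-07), Hspa1a by 3.15 (SE 0.35, adjusted p = 3.42e-06), Dnajb1 by 2.03 (SE 0.27, adjusted p = 5.26e-05) and Hspe1 by 1.27 (SE 0.19, adjusted p = 2.01e-04). The list passed camera at adjusted p = 1.51e-08 and held, at adjusted p = 0.017 with an estimated correlation. Cyp51 fell in the cholesterol synthesis list, where 20 of 22 genes were lower and 5 fell when adjusted over the list alone (camera adjusted p = 5.27e-07, adjusted p = 0.13 with an estimated correlation). Cox6c and Cox8a, subunits of cytochrome oxidase, fell among 56 genes of oxidative phosphorylation, and 2 when adjusted over the list alone (camera adjusted p = 9.23e-04, adjusted p = 0.23 with an estimated correlation). Of 82 ribosomal protein genes 10 fell, and 14 fell and 1 rose when adjusted over the list alone, with Rpl35 from 1953 ± 87.8 to 918 ± 195 CPM (camera adjusted p = 0.00586, adjusted p = 0.41 with an estimated correlation). Eno1 fell in the glycolysis list (1 of 22, 5 when adjusted over the list alone; camera adjusted p = 0.00527, adjusted p = 0.41 with an estimated correlation). It can share reads with Eno1b, and the sum of both was 471 ± 78.5 and 356 ± 52 CPM of the library total (exact permutation p = 0.2). Atf5 fell in the amino acid list (1 of 17, and 1 when adjusted over the list alone) and no proliferation gene of 34 was called, also when adjusted over the list alone. These lists passed camera downward at adjusted p = 0.0175 and 0.0365, each with adjusted p = 0.28 with an estimated correlation. Utp14b, Gipc1, Or2w1b, Med16, Hsph1, Rab13 and Rps27 were also among the largest falls, the last with the doubt on its copy given above. The fall of AU022252 was 2.87 on the log2 scale. With the macrophage covariate 8 genes were called. For the 175 genes the median absolute log2 fold change went from 1.55 to 1.22 and the median SE from 0.35 to 0.643, and 167 kept their sign. Leaving out young replicates 1, 2 and 3 in turn gave 109, 89 and 107 calls, and leaving out restricted replicates 1 and 3 gave 95 and 92.

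The last comparison set the restriction changes beside the age changes. Stc1 and Igfbp3 rose with age and fell with restriction. The summed endothelium list moved the same way, at 127 ± 34.5, 510 ± 236 and 216 ± 123 CPM in young, aged ad libitum and restricted mice (SD, n = 3). Whether a changed share of endothelial RNA accounts for such genes was not tested. Retnla and H2-Eb1 fell with age and rose with restriction, and Lgals7, named after its values were seen, rose in both. Hmgn2 also fell and then rose, but this is uncertain: with its pseudogene the sum moved by -0.948 and 1.15 on the log2 scale, against -2.81 and 3.25 for Hmgn2 alone. The heat shock genes Hspa1a, Hspa1b and Dnajb1 were called lower in both aged groups than in young mice. Of the 26 genes called with age, 14 had the opposite sign with restriction and 6 were also called there, 5 of them in the opposite direction. Age and restriction share the aged ad libitum libraries, which favours opposite signs with no effect at all. In 100 simulations of unchanged groups, as many genes were taken by smallest p as were called in the data. There 24.5 of 26 genes (SD 1.23) had opposite signs and 5.89 (SD 2.15) were shared in opposite directions, so these counts do not show a reversal. Independent lists would share 0.033 genes up then down, 0.089 down then up and 0.089 up in both. Of the 26 genes, 16 were also called between aged restricted and young mice, all in the same direction. Those contrasts share the young libraries, and the simulations shared 7.48 genes in the same direction (SD 2.25, range 2 to 14), against 0.14 up and 0.11 down for independent lists. Over all 9009 genes the log2 fold changes of age and restriction had r = -0.41, less negative than in any simulation (-0.551 to -0.488). Their covariance of -0.29 was more negative than the simulated mean of -0.23 (SD 0.0083), by a difference of -0.061. All these simulations drew each gene on its own, without the correlation between genes. Their SDs and ranges are therefore too narrow to judge the differences from the data, including that of the shared genes. The simulated r and covariance also came from another edgeR fit than those of the data. The covariance was -0.196 at a minimum of 10 CPM, -0.619 without aged ad libitum replicate 1 and -0.591 without its replicate 3, settings for which no simulated value was made. This r is across genes, which are not independent replicates. Neither shared group of 3 libraries can be split into parts of at least 2 each, so part of each overlap may come from the shared libraries.

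**Figure D3:**
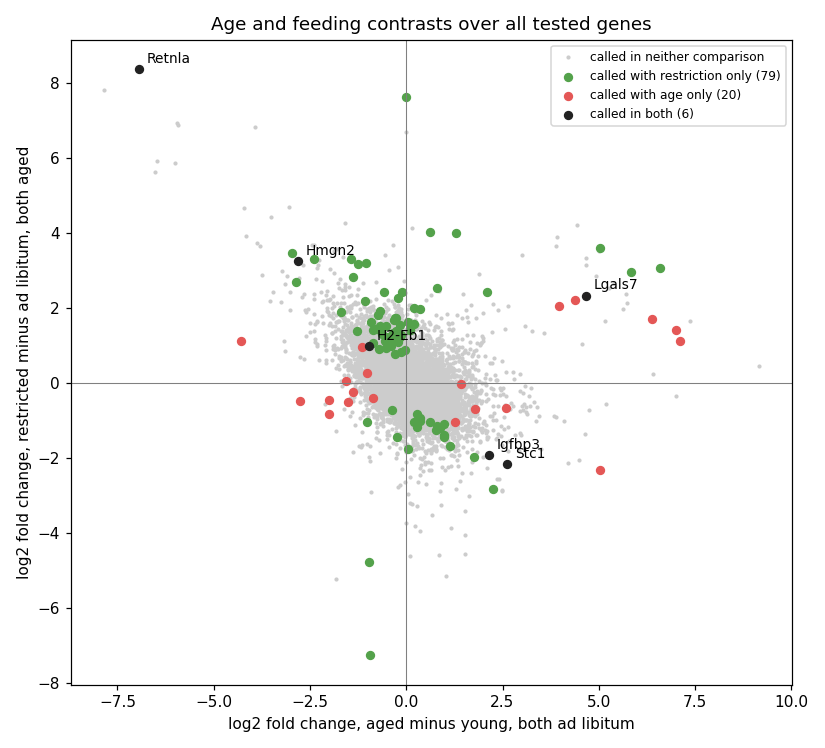
Log2 fold change with age (horizontal axis) against log2 fold change with restriction (vertical axis) for 9009 genes, with called genes in colour and the 6 genes called in both comparisons named. Retnla, H2-Eb1 and Hmgn2 lie at the upper left, Stc1 and Igfbp3 at the lower right; Retnla and other genes with a group at 0 counts are drawn at fitted values, which are no bounds.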

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

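Leaving out the mitochondrial genes and thinning the libraries were chosen only after the results were seen, and all other alternatives earlier. The 26 genes called with age became 126 with no filter, 91 by DESeq2, 47 by voom, 61 with only the 2 groups compared and 64 with the macrophage covariate, and 2 (without young replicate 2) to 30 (without aged ad libitum replicate 2) with 1 library left out. They were 18 and 9 without young replicates 1 and 3, and 3 without aged ad libitum replicate 3. The 85 genes called with restriction became 50 with library totals, 224 with no filter, 171 by DESeq2, 137 by voom, 54 with only the 2 groups compared and 1 with the macrophage covariate. With 1 library left out they were 25 (without aged ad libitum replicate 2) to 148 (without restricted replicate 2), and 42 (without aged ad libitum replicate 3), 31 and 50 (without restricted replicates 1 and 3). The 175 genes called between restricted and young mice became 286 with no filter and 8 with the covariate, and 89 (without young replicate 2) to 234 (without restricted replicate 2). They were 109 and 107 without young replicates 1 and 3, and 95 and 92 without restricted replicates 1 and 3. With no filter more genes were tested, and with a library left out fewer libraries were; for the others the cause was not tested. The upper quartile, DESeq2 size factors, the minimum of 10 CPM, the minimum fold, the left-out mitochondrial genes and the thinned libraries each kept all 3 counts within 1.5 times. No gene called both in the reported analysis and in an alternative changed its sign.

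With the replicate block the counts were 49 with age, 133 with restriction and 223 between restricted and young mice. The labels give no pairing by replicate number, and the reported model used none. The 9 pairs with the same number had correlations of -0.0281 to 0.0772, and the other pairs -0.0768 to 0.047. Of the 9 libraries, 7 correlated best with a library of their own number. That is a hint, from the data and not the design, of structure shared by number, which the reported model does not take up.

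Of the lists, 9 passed with age, 15 with restriction and 20 between restricted and young mice. With an estimated correlation 1, 0 and 1 passed, and by fry 2, 1 and 11. With 1 library left out the counts ran from 6 (without aged ad libitum replicate 1) to 14 (without aged ad libitum replicate 2) with age. With restriction they ran from 7 (without aged ad libitum replicate 2) to 18 (without restricted replicate 2), with 9 without restricted replicate 1. Between restricted and young mice they ran from 13 (without young replicate 2) to 21 (without restricted replicate 2). The r of -0.409 between age and restriction was -0.365 at a minimum of 10 CPM, and -0.599 (without aged ad libitum replicate 1) to -0.324 (without young replicate 1). With the macrophage covariate, 3 of the named genes called between restricted and young mice turned negative: Ccl3 at -0.50, Srgn at -0.31 and Ctss at -0.0639 (edgeR adjusted p = 0.907, 0.911 and 0.983). Of all genes called in that comparison 167 of 175 kept their sign with the covariate, and of those called with restriction 83 of 85. The cause of the turned signs was not tested. The other values of named genes numbered 7182 on the same side of the threshold, 460 weaker and 211 stronger, and those of lists 806, 127 and 24. Lag3, Tox and Tcf7 fell under the count filter, so they were not tested.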

Other observations

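Each test of an explanation below was chosen only after the pattern was seen, apart from the other splits of the libraries, which were planned.

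Several lists fixed beforehand have not been described. In the senescence and inflammatory secretion list, restriction raised Ccl2, a chemokine for monocytes, from 243 ± 106 to 484 ± 50.7 CPM (SD, n = 3) and lowered Igfbp3, with 4 up and 1 down when adjusted over the list alone (camera adjusted p = 0.168). Between restricted and young mice Lamp1 and Ctsb, a lysosomal membrane protein and a lysosomal protease, rose among 24 autophagy and lysosome genes, 3 when adjusted over the list alone (camera adjusted p = 0.0668). Ctsb went from 266 ± 17.4 CPM in young to 600 ± 60.5 CPM in restricted mice. In the same comparison Cd74 rose as the 1 called gene of 6 in the MHC class II list, and 1 when adjusted over the list alone (camera adjusted p = 0.18). Sparc fell as the 1 called gene of 11 in the fibroblast list, with 1 up and 1 down when adjusted over the list alone (camera adjusted p = 0.163). The dendritic cell list (4 tested genes) and the fatty acid oxidation list (23) had no called gene in any comparison, also when adjusted over the list alone. Dendritic cell genes summed to 483 ± 92.9, 413 ± 80.4 and 414 ± 74.7 CPM and circadian clock genes to 88.1 ± 12.1, 135 ± 25.9 and 119 ± 49.5 CPM in young, aged ad libitum and restricted mice.

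The called genes named next were chosen after their values were seen. Fads2, a fatty acid desaturase, stood at 320 ± 10.1, 157 ± 41.1 and 75.8 ± 9.28 CPM in young, aged ad libitum and restricted mice (SD, n = 3), called with restriction (edgeR adjusted p = 0.0355) and between restricted and young mice (adjusted p = 1.23e-05). Ccnd1, the G1 cyclin D1, stood at 567 ± 52.6, 408 ± 77.2 and 232 ± 44.3 CPM, called between restricted and young mice (adjusted p = 4.53e-04). B2m, the light chain of MHC class I, rose with restriction from 2876 ± 348 to 5086 ± 372 CPM (adjusted p = 0.00163). Selenop, a selenium carrier, rose from 65.2 ± 17.6 to 265 ± 130 CPM, and Fcgr4, an activating Fc receptor, from 16.8 ± 4.44 to 92.1 ± 15.3 CPM.

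Macrophage genes were higher in restricted than in ad libitum aged mice, and the question was whether macrophage RNA as a whole took a larger share. A second list of 39 macrophage genes, disjoint from the first, had 38 (97.4%, exact 95% binomial interval 86.5 to 99.9) higher in restricted mice. Of the 30 called in no comparison, 29 (96.7%) were higher. The interval treats genes as independent, while the first list had an estimated correlation of 0.471 between genes. It therefore does not measure the spread between libraries. The higher second list goes with a larger share of macrophage RNA in these samples, whether from the tumour or from the separation. The data cannot tell these sources apart. Without aged ad libitum replicate 2, the mean log2 level of the first list was still higher by 0.879 (95% t interval over libraries 0.338 to 1.42), which argues against 1 library poor in macrophages as the only cause. For the T cell identity list the difference was 0.719 (-0.902 to 2.34), which cannot decide on a lower share of T cell RNA. A lower share alone would raise the lists of all other cells together. Fibroblast genes stood at 2055 ± 439 CPM in aged ad libitum and 1797 ± 1048 CPM in restricted mice (SD, n = 3). Endothelial genes stood at 510 ± 236 and 216 ± 123 CPM, and red blood cell genes at 71.2 ± 25.1 and 287 ± 113 CPM. Such unlike moves argue against a lower T cell share as the only cause.

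Heat shock genes were lower in aged than in young mice fed ad libitum. The log2 ratio of the summed Hspa1a and Hspa1b levels was -3.21, which argues against reads shared between the 2 copies as the cause. Handling stress of the young samples that also raised immediate-early genes predicted a lower immediate-early list in aged mice, and the difference of its mean log2 level, 0.347 (95% t interval over libraries -0.144 to 0.838), cannot decide this. Stress during digestion that spares those genes, and an effect of age on the response, both remain open.

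Skin and muscle genes were higher in restricted than in young mice, and tissue taken along with the tumour was weighed. Second lists of skin and muscle genes, disjoint from the first, had 46 of 49 (93.9%, exact 95% binomial interval 83.1 to 98.7) higher in restricted mice. Of the 48 called in no comparison, 45 (93.8%) were higher. This interval also treats genes of the same libraries as independent, so it does not measure the spread between libraries. The skin part went from 62.2 ± 3.76 to 256 ± 103 CPM with 25 of 25 genes higher, and the muscle part from 122 ± 13.8 to 155 ± 46.1 CPM with 21 of 24 higher, so skin tissue carried over with the tumour is consistent with the values and the case for muscle is weaker. In the second skin list the lowest restricted library stood at 2.15 times the highest young library, which argues against 1 library alone. In the second muscle list it stood at 0.829 times, which leaves that open for its genes. The first muscle list stood at 650, 148 and 271 CPM in the restricted libraries and 13.1, 34.9 and 21.4 CPM in the young libraries, so its rise was not in 1 library alone. Aged ad libitum mice also had 17 of 18 detected genes of the second skin list higher than young mice, at 103 ± 48.3 against 62.2 ± 3.76 CPM. Carried-over skin thus stays possible for Krt14 and Krt17 with age too. In the second muscle list 8 of 16 detected genes were higher in aged ad libitum than in young mice, at 101 ± 18.9 against 122 ± 13.8 CPM. The higher first muscle list in aged ad libitum mice (102 ± 53.4 against 23.1 ± 11 CPM) was thus not matched by the second. No biological explanation was tested.

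A further hypothesis was less effector RNA per T cell with restriction. Effector genes per T cell core transcript stood at 1.36 ± 0.224, 1.16 ± 0.232 and 0.877 ± 0.167 in young, aged ad libitum and restricted mice (SD, n = 3), with an exact permutation p = 0.2 for restriction, which cannot decide it. Among the 10 splits of 6 libraries, the real one was the 1 with as many genes in each comparison: 26 with age against 2 for the highest other split, 85 with restriction against 0, and 175 between restricted and young mice against 2. With 10 splits a share under 0.05 cannot be reached.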
